A study of Oryctolagus cuniculus with 24 samples.

How the data were processed

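Primary rabbit corneal keratocytes in 3 culture conditions were measured by RNA sequencing, with 8 libraries per condition. The labels' protocols give the culture, the column-based RNA kit and a sequencing company for the libraries. The aligner, the counting program, the genome build and the annotation are not given in the sources used here. The deposited count table holds 1 integer count per gene and library, with no normalization, per the file headers and values. The deposited FPKM table holds the same counts divided by gene length and by a library size that the authors scaled per library, which lies close to the effective library sizes computed here with TMM. The main results rest on the counts, and FPKM values served only as an alternative.

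Gene names are those of the table. A gene listed only by number was given a symbol where the RefSeq table pairs the number with one (700 of 8020 such identifiers). The 39 gene lists were fixed before the data were examined and hold 803 genes, of which 50 are not in the table under any name tried and 25 were found by gene number. ALDH3A1 is among the genes not analysed here.

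Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the condition as the group (13308 genes), library sizes were scaled by TMM, and all 24 libraries were fitted together with 1 coefficient per condition. Each of the 3 comparisons was tested with the quasi-likelihood F-test, and p-values were adjusted by Benjamini and Hochberg over all genes tested. A gene is called higher or lower at an adjusted p under 0.05. "At least 2-fold" adds an absolute log2 fold change of 1 or more. Standard errors come from the same fit. Counts scaled to library size (CPM) use the TMM sizes and given as mean ± SD of the libraries of a condition. List members that rose or fell are those called in the test over all genes, and the same counts were also made with p-values adjusted over the list alone.

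Each list with 3 or more tested members was tested with camera (limma 3.58.1) at the preset correlation between genes of 0.01, with p-values adjusted over the lists of that comparison. Camera was repeated with a correlation estimated per list, and fry was run as a self-contained test. Differences of an effect between the sets of library numbers were tested with a set-by-treatment term in edgeR for genes and with camera on that term for lists. Principal components were taken from log2 CPM of all genes kept. Where a condition had 0 counts in all libraries, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts the ratio has a 95% interval from the binomial distribution of counts.

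The genes named in the text follow a rule fixed before the data were examined. For each comparison it takes the 10 genes with the largest rise and the 10 with the largest fall among named genes past the threshold, with a mean of at least 5 CPM in the higher group and no overlap of the libraries. It adds up to 4 called members of each list with the largest change and up to 2 members that did not pass with the highest level. It also adds up to 5 genes in each direction called with opposite signs against serum-free medium in the treatments, and a fixed set of markers of keratocytes, fibroblasts and myofibroblasts. The text leaves out some of these genes, most of them for room and a few for reasons other than their values. Genes named by the rule in one comparison are also given in the others. PTPRC, CD74, TYROBP and CYBB are outside the rule and were chosen after the values were seen. MATN1, LAPTM4A, LAPTM4B and the FOXO targets of the closing part are outside it too. Their tests were chosen after LAPTM5, PDK4 and PIK3IP1 had been seen, and written down before the values of the tests were looked at.

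Replicate numbers might pair the samples across conditions. The residuals of same-numbered libraries, after the condition means were removed, correlated at 0.177 to 0.362, 0.115 to 0.429 and 0.103 to 0.332 in the 3 pairs of conditions, so the number was also used as a block. A library's best match was its own number in 6, 7 and 6 of 16 cases, and within the sets of library numbers 5 to 8 and 9 to 12 the correlations were -0.109 to 0.23. With the replicate block the calls were 4626 higher and 4759 lower for TGF-β1 against serum-free, 5488 and 5616 for FBS against serum-free, and 5243 and 5068 for TGF-β1 against FBS. No library duplicates another: the lowest chi-square per gene (squared difference over counting variance) within a condition was 2.85. FBS replicates 1 and 2 (2.85), 3 and 4 (3.41) and 7 and 8 (3.12) were close, however. So were TGF-β1 replicates 5 and 6 (3.34) and 7 and 8 (3.79). TGF-β1 (18.8) and serum-free (16.6) replicates 1 and 2 were not. What close pairs share was not tested, so 8 libraries may stand for fewer separate units. Leaving out 1 library keeps its close neighbour.

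The edgeR and camera steps were tested on simulated data first, with counts drawn from the real means, dispersions and library sizes and with 200 genes changed by known folds per treated condition. For TGF-β1 against serum-free, 51.6% of genes changed 1.5-fold, 76.9% of those changed 2-fold and 100% of those changed 4-fold were recovered over 12876 genes. The shares were 42.4%, 89.2% and 98.4% for FBS against serum-free, and 53.8%, 83.1% and 98.4% for TGF-β1 against FBS. Of the calls in the same order, 5.19%, 5.70% and 5.90% were false. The simulated libraries were drawn independently from the serum-free means, with few genes changed. The real comparisons called 64.3% to 80% of genes, and the real libraries differed between the sets. The simulated shares therefore do not measure the error of the real calls. No list was changed as a list in the simulation, and camera called 1, 0 and 0 of 38 lists. The simulated genes were drawn independently of each other. Real lists held correlated genes, with an estimate of 0.793 for cholesterol synthesis in TGF-β1 against serum-free. False calls of correlated lists were therefore not tested by the simulation. Genes with few counts have the largest counting error, which their intervals give, and the filter removes most of them.

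The alternatives fixed before the data were examined were other size factors, total library size only, no filter and a stricter filter (at least 1 CPM in 8 libraries), only the 16 libraries of the conditions compared, the replicate block, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), each library left out in turn, the estimated correlation and fry for lists, and the serum-free libraries divided between the comparisons for the overlap. Chosen after seeing the data were the set as a covariate, each set alone, counts summed per condition and set, FBS replicates 5 and 6 left out, and the estimated correlation for the set-by-treatment term of lists. All fits ran on 1 thread with fixed seeds. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. GC content was not used here.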

Results

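RNA was sequenced from primary rabbit corneal keratocytes, the resident cells of the corneal stroma, in 24 libraries. The cells were grown for 6 days at the first passage on glass coated with collagen, in 3 culture conditions with 8 libraries each. Serum-free medium is the keratocyte condition of the labels. TGF-β1 at 5 ng/mL in serum-free medium from day 1 is the myofibroblast condition, and DMEM with 10% fetal bovine serum (FBS) from day 3 is the fibroblast condition. The FBS arm therefore differs from the others in base medium and in days of exposure as well as in serum. Nothing in the labels says that the replicates came from separate animals or cultures, so every p-value below measures only the spread between these samples, which may be technical.

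Total counts per library ran from 17151397 to 21540864 in serum-free medium, from 15410285 to 20911192 with TGF-β1 and from 15659561 to 22528261 with FBS. Transcripts of type I collagen (COL1A1 and COL1A2), the main fibrillar collagen of the stroma, took 12.1% ± 1.72 of all counts in serum-free medium, 10.5% ± 0.919 with TGF-β1 and 1.09% ± 0.321 with FBS (mean ± SD, n = 8). The 10 most abundant genes took 24.3% ± 2.86, 20.9% ± 0.665 and 7.08% ± 0.482 of the counts in the same order. In all, 13308 genes had enough counts to be tested. The libraries fell into their groups on the first principal components, of which the leading pair held 58.3% and 24.8% of the variance. Correlations of log2 CPM were 0.948 to 0.993 within groups and 0.743 to 0.893 between groups. The column names number the libraries 5 to 12 in each condition, and on the next component (5.75%) numbers 5 to 8 (set 1) stood apart from numbers 9 to 12 (set 2) in all 3 conditions. Gene length ran with the sets: the Spearman correlation of length with a library's deviation from its condition was -0.0729 to 0.433 in set 1 and -0.528 to 0.0646 in set 2, lowest in FBS replicates 5 and 6. Those libraries also stood apart from FBS replicates 7 and 8 of their set, with a chi-square per gene of 47.3 to 74.9 against 3.12 between the latter. Values within each set are therefore given beside many of the pooled ones. Each set was fitted alone with its own filter (13478 genes in set 1 and 13501 in set 2). The tested members of a list can therefore differ from the pooled ones, and both set medians can lie on 1 side of the pooled median.

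**Figure D1:**
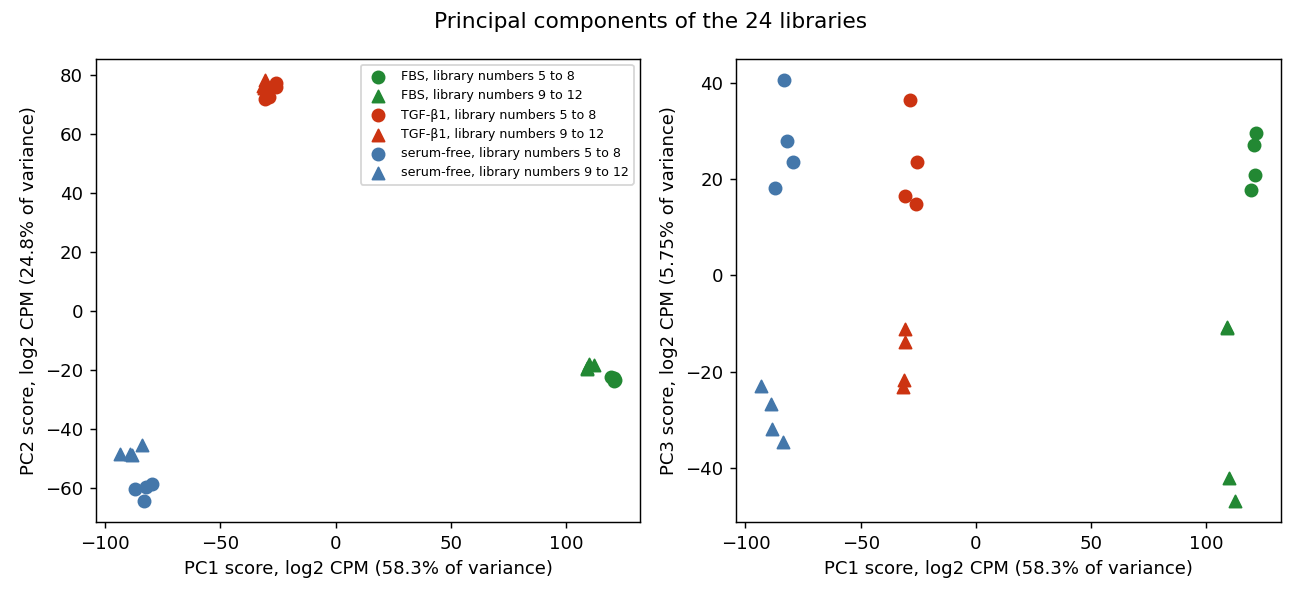
Scores of the 24 libraries on the first 3 principal components of log2 CPM, coloured by culture condition, with circles for libraries 5 to 8 and triangles for libraries 9 to 12. The conditions separate on PC1 (58.3% of the variance) and PC2 (24.8%), and the library numbers separate on PC3 (5.75%).

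What TGF-β1, a growth factor that turns fibroblasts into contractile myofibroblasts, changed in serum-free keratocytes is the question of the first comparison. ACTA2, which encodes α-smooth muscle actin, rose from 2.92 ± 2.10 to 231 ± 125 counts scaled to library size (CPM, mean ± SD, n = 8 here and below), a log2 fold change of 6.29 (SE 0.48, edgeR adjusted p = 1.01e-11). TAGLN, an actin-binding protein of smooth muscle, rose from 3.40 ± 2.52 to 411 ± 136 CPM (log2 fold change 6.91). KERA, the keratan sulfate proteoglycan keratocan, fell from 8807 ± 1328 to 293 ± 46.2 CPM (-4.91, SE 0.25, edgeR adjusted p = 2.58e-15). LUM, which encodes lumican, fell from 13318 ± 1603 to 6862 ± 1352 CPM (-0.96, adjusted p = 7.53e-05). In the coordinates of the deposited table, whose genome build is not given in the sources used here, ACTA2 lies on chromosome 18 at 36853676 to 36870691 and KERA on chromosome 4 at 70262575 to 70269568.

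Of the 13 keratocyte markers tested, 12 fell and 1 rose with TGF-β1 (median log2 fold change -2.15, -1.71 in set 1 and -2.44 in set 2, camera adjusted p = 5.27e-09). OGN, the small proteoglycan osteoglycin, fell from 25503 ± 7451 to 1498 ± 551 CPM (-4.09). The retinal dehydrogenase and corneal crystallin ALDH1A1 fell from 1312 ± 212 to 186 ± 12.5 CPM (-2.82), and the surface sialomucin CD34 from 240 ± 15.9 to 6.12 ± 0.734 CPM (-5.29). THY1, a surface glycoprotein often used to mark fibroblasts, also fell (-0.97, adjusted p = 0.00441). The small leucine-rich proteoglycans did not move as a group: 4 of 11 rose and 7 fell (median -1.31, -0.98 in set 1 and -1.61 in set 2, camera adjusted p = 0.47, and 0.0224 in set 2 alone). BGN (3.97), ASPN (4.42), FMOD (2.37) and PRELP (2.01), which encode biglycan, asporin, fibromodulin and prolargin, were the members that rose.

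Genes known to answer TGF-β rose together, 16 of 18 tested with 1 lower (median 3.11, 3.38 in set 1 and 3.16 in set 2, camera adjusted p = 2.32e-17). LTBP2, a latent TGF-β binding protein of microfibrils, went from 3.48 ± 1.11 to 1996 ± 235 CPM, 571-fold. CTGF, a matricellular growth factor, rose by 5.10 on the log2 scale and CDKN2B, an inhibitor of cyclin-dependent kinases, by 6.70. TGFBI, a corneal matrix protein named for its induction by TGF-β, was 491 ± 92.1 CPM without and 548 ± 221 CPM with it (0.16, adjusted p = 0.485). It fell in set 1 (-0.28) and rose in set 2 (0.41), and the set-by-treatment term passed (edgeR adjusted p = 2.09e-05). Of 9 BMP target genes 8 rose (median 2.78, 2.39 and 3.01 in the sets, camera adjusted p = 9.85e-05, but adjusted p = 0.0809 with an estimated correlation). ID2 (4.29) and ID3 (4.44), inhibitors of helix-loop-helix factors, were among them. Smooth muscle contractile genes rose in 14 of 21 cases and fell in 4 (median 1.28, 1.53 and 0.87 in the sets, camera adjusted p = 1.18e-05, but adjusted p = 0.0759 with an estimated correlation). ACTG2, an enteric actin, rose by 6.39, and MYLK, myosin light chain kinase, fell (-4.07). Of 18 immediate early genes of the serum response factor, 13 rose and 1 fell (median 0.85, 1.03 and 1.30 in the sets, camera adjusted p = 0.00242, but adjusted p = 0.238 with an estimated correlation). NR4A1, a nuclear receptor, rose by 3.75, while EGR1, a zinc finger factor, averaged 125 ± 133 and 138 ± 52.2 CPM (0.14, adjusted p = 0.779, with 1.44 in set 2, where it passed).

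Among matrix genes, the list of collagen processing passed with TGF-β1 and the list of collagens did not. Collagen processing and crosslinking genes rose in 16 of 22 cases and fell in 2 (median 1.09, 0.77 in set 1 and 1.12 in set 2, camera adjusted p = 3.08e-10). Among them PLOD2, which hydroxylates the lysines used for crosslinks, went from 6.97 ± 1.61 to 806 ± 135 CPM (6.85), P4HA3, a prolyl hydroxylase subunit, rose by 7.42 and TGM2, a transglutaminase, by 6.80. Of 24 collagens 12 rose and 7 fell, and the list did not pass (median 0.51, 0.40 and 0.46 in the sets, camera adjusted p = 0.202, and 0.0259 in set 2 alone). COL1A1 was 63482 ± 10458 CPM in serum-free medium and 69759 ± 5402 CPM with TGF-β1 (0.14, adjusted p = 0.412). Its log2 fold change was -0.10 in set 1 and 0.40 in set 2, where it passed. COL1A2 did not pass either (-0.33, adjusted p = 0.0878), with -0.66 in set 1, where it passed, and 0.03 in set 2. It also passed with total library size only, with only the 16 libraries compared and with the set as a covariate. COL3A1, the collagen of early wounds, rose from 17.6 ± 4.80 to 53.7 ± 11.7 CPM (1.61).

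Matrix glycoproteins rose with TGF-β1 in 16 of 28 cases and fell in 7 (median 0.52, 0.77 and 0.54 in the sets, camera adjusted p = 0.00701, but adjusted p = 0.0809 with an estimated correlation). FN1, fibronectin, rose 4.00-fold to 21157 ± 3768 CPM, and POSTN (6.63), VCAN (4.99) and ELN (5.06), which encode periostin, versican and elastin, rose too. Matrix proteases and their inhibitors rose in 15 of 22 cases and fell in 5 (median 1.47, 1.71 and 1.55 in the sets, camera adjusted p = 3.19e-05). The urokinase receptor PLAUR (6.44) and the metalloprotease ADAM12 (6.52) were among the higher. Integrins and focal adhesion genes rose in 17 of 31 cases and fell in 6 (median 0.50, 0.55 and 0.71 in the sets, camera adjusted p = 0.000935, but adjusted p = 0.0852 with an estimated correlation). The integrin subunit gene ITGB3 rose by 6.78 and ITGA2 fell (-4.42). Glycosaminoglycan synthesis genes rose in 13 of 24 cases and fell in 6 (median 0.44, 0.64 and 0.40 in the sets, camera adjusted p = 0.00701, but adjusted p = 0.0811 with an estimated correlation). The hyaluronan synthase HAS2 rose by 5.22. Cartilage, bone and tendon genes rose in 10 of 15 cases and fell in 5 (median 2.18, 2.26 and 2.72 in the sets, camera adjusted p = 0.00605, but adjusted p = 0.0934 with an estimated correlation). SPP1, osteopontin, went from 0.869 ± 0.606 to 235 ± 24.5 CPM (8.05), and ACAN, aggrecan, rose by 6.40. IBSP, bone sialoprotein, had 0 counts in serum-free medium and 2127 with TGF-β1, at least 843-fold more against a floor of 3 counts over the group. The list's median stays at 2.18 with IBSP at that bound, an outcome fixed in advance because the bound lies far above the median.

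Lists of lipid synthesis, stress response and p53 target genes rose as well. Cholesterol synthesis and uptake genes rose in 19 of 22 cases and fell in 1 (median 1.33, 0.95 in set 1 and 2.10 in set 2, camera adjusted p = 0.000221, but adjusted p = 0.432 with an estimated correlation), and the effect was larger in set 2 (camera on the set-by-treatment term, adjusted p = 8.83e-55, and 1.45e-05 with an estimated correlation). Fatty acid synthesis genes rose in 11 of 12 cases and fell in 1 (median 1.86, 1.46 and 2.31 in the sets, camera adjusted p = 7.21e-09). ACSS2, an acetyl-CoA synthetase, rose by 3.02. Glycolysis genes rose in 13 of 21 cases and fell in 3 (median 0.58, 0.72 and 0.44 in the sets, camera adjusted p = 0.000543, but adjusted p = 0.131 with an estimated correlation). The lactate exporter SLC16A3 rose by 4.04. The unfolded protein response rose in 18 of 20 cases and fell in 1 (median 0.56, 0.59 and 0.54 in the sets, camera adjusted p = 0.000149, but adjusted p = 0.0907 with an estimated correlation). The amino acid starvation response rose in 14 of 19 cases and fell in 1 (median 1.55, 1.05 and 1.55 in the sets, camera adjusted p = 7.38e-05, but adjusted p = 0.298 with an estimated correlation). TRIB3, a pseudokinase of the latter response, rose by 4.00. Targets of p53 rose in 12 of 17 cases and fell in none (median 1.07, 1.48 and 1.01 in the sets, camera adjusted p = 0.000164). The cell cycle inhibitor CDKN1A rose from 124 ± 61.7 to 1252 ± 145 CPM (3.34). Wnt pathway genes rose in 14 of 24 cases and fell in 8 (median 0.61, camera adjusted p = 0.0252). That call was lost with the replicate block (adjusted p = 0.0681), within either set (0.121 and 0.0828, medians 0.51 and 0.69), with DESeq2, with FPKM values and at adjusted p = 0.0759 with an estimated correlation. WNT2, a Wnt ligand, rose by 6.67.

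Complement genes fell in 10 of 14 cases and rose in 3 (median -1.68, -1.42 in set 1 and -1.70 in set 2, camera adjusted p = 0.04, but adjusted p = 0.351 with an estimated correlation). The call was also lost with total library size only and with DESeq2. C3, the central complement component, fell from 55.5 ± 10.5 to 9.44 ± 2.79 CPM (-2.55). PTPRC, a surface phosphatase of leukocytes, averaged 0.147 ± 0.130, 0.0288 ± 0.0814 and 0.0971 ± 0.0749 CPM in serum-free medium, with TGF-β1 and with FBS. Glial, Schwann and melanocyte markers fell in 7 of 10 cases and rose in 1 (median -1.52, -1.88 and -1.29 in the sets, camera adjusted p = 0.0444). That call was lost with the replicate block (adjusted p = 0.0792), at adjusted p = 0.35 with an estimated correlation, in set 2 alone (0.0924) and in 16 of 40 alternative settings in all, 7 of which left out a single library. Of 5 immune cell markers 2 rose and 1 fell (median 0.36, -0.13 and 0.65 in the sets, camera adjusted p = 0.0139, but adjusted p = 0.0809 with an estimated correlation). The call was also lost with no filter, with FPKM values, with counts summed per condition and set and without FBS replicates 5 and 6, at adjusted p up to 0.87. LAPTM5, a lysosomal protein best known from blood cells, rose from 4.01 ± 1.09 to 305 ± 50.2 CPM (6.24). Vascular endothelial markers did not pass (1 of 5 rose and 3 fell, median -1.11, 0.06 and -1.47 in the sets, camera adjusted p = 0.222).

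Mitotic genes did not pass as a list with TGF-β1. None of 28 rose and 9 fell (median -0.80, camera adjusted p = 0.351). The effect differed between the sets (camera on the set-by-treatment term, adjusted p = 2.39e-11, but 0.074 with an estimated correlation): the median was -1.08 in set 1 (adjusted p = 0.00972) and 0.34 in set 2 (adjusted p = 0.768). MKI67, a nuclear protein of dividing cells, averaged 6.72 ± 6.86 CPM in serum-free medium and 3.01 ± 1.55 CPM with TGF-β1 (-1.15, adjusted p = 0.0658, with a call in 8 of 38 alternative settings). Its change was -1.59 in set 1, where it passed, and 0.99 in set 2 (set-by-treatment adjusted p = 0.00225). DNA replication genes rose in 4 of 26 cases and fell in 11 (median -0.52, -0.97 and 0.22 in the sets, camera adjusted p = 0.408, and 0.0246 in set 1 alone, set-by-treatment adjusted p = 8.3e-11, and 0.0146 with an estimated correlation). Oxidative phosphorylation (11 of 20 rose, median 0.29, camera adjusted p = 0.143, with a call when no filter, FPKM values, fry or summed counts were used) and housekeeping genes (10 of 17 rose and 2 fell, median 0.30, camera adjusted p = 0.147, and 0.0461 in set 1 alone) did not pass as lists. Inflammatory cytokines and chemokines rose in 6 of 14 cases and fell in 7 (median -0.16, mean 0.76, camera adjusted p = 0.191 with its direction up), and passed upward as a list within each set (0.0298 and 0.0426, medians 0.63 and -0.29). CCL2, a chemokine that draws monocytes, fell (-3.18). IGF and insulin signaling genes rose in 8 of 19 cases and fell in 7 (median -0.11, camera adjusted p = 0.777), with IGF1 up by 2.68.

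Over all genes, edgeR's quasi-likelihood test called 4155 genes higher and 4408 lower with TGF-β1 at an adjusted p under 0.05, 64.3% of those tested, and 3470 of them changed at least 2-fold. In 4505 genes all 8 libraries of one group lay above all 8 of the other. Chance would give this in 0.0155% of genes if the libraries were independent, but they clustered by set and may be technical repeats. That share is therefore not a measure of chance here. Scaled by total library size only, the split was 3215 higher and 5368 lower (37.5% against 48.5% higher), with the median of all genes at -0.17. Adjusted over the list alone, the counts above were the same except for 17 collagen processing genes and 19 unfolded protein response genes that rose and 6 mitotic genes that fell. Other genes of the largest changes were CR2, a complement receptor, from 0.571 ± 0.580 to 1245 ± 145 CPM (11.09), ANKRD1, a stretch-responsive nuclear protein (9.21), and, downward, IL18R1, the interleukin-18 receptor (-7.22), and FAM20A, a pseudokinase of the secretory pathway (-6.94).

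What serum, with its change of base medium, did to the same cells is the question of the next comparison. Genes of cell division rose from low levels: MKI67 went from 6.72 ± 6.86 to 425 ± 153 CPM (log2 fold change 5.98, SE 0.58, edgeR adjusted p = 4.34e-10), and CDC20, an activator of the anaphase-promoting complex, from 2.06 ± 2.14 to 228 ± 23.6 CPM (6.77). Type I collagen fell, with COL1A1 down from 63482 ± 10458 to 5862 ± 1593 CPM (-3.44, SE 0.16, edgeR adjusted p = 7.61e-17) and COL1A2 from 61668 ± 11891 to 3545 ± 1207 CPM (-4.12). Keratocyte genes fell too, KERA to 237 ± 113 CPM (-5.21), LUM to 832 ± 329 CPM (-4.00) and OGN to 115 ± 38.7 CPM (-7.79). ACTA2 rose to 479 ± 221 CPM (7.35, SE 0.50, edgeR adjusted p = 3.19e-13) and TAGLN to 258 ± 75.1 CPM (6.24). COL1A1 lies on chromosome 19 at 37474894 to 37490691 and LUM on chromosome 4 at 70315437 to 70323221.

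All 28 mitotic genes rose with FBS (median 5.56, 5.09 in set 1 and 7.07 in set 2, camera adjusted p = 1.93e-10, but adjusted p = 0.178 with an estimated correlation), and all 26 DNA replication genes (median 4.00, 3.98 and 4.30 in the sets, camera adjusted p = 4.05e-17). CCNB1, cyclin B1, rose by 6.59, MCM5, a replicative helicase subunit, by 5.19 and PCNA, the polymerase clamp, from 30 ± 2.96 to 263 ± 17.2 CPM (3.13). All 20 oxidative phosphorylation genes rose (median 1.11, 0.98 and 1.19 in the sets, camera adjusted p = 0.00117, but adjusted p = 0.378 with an estimated correlation). NDUFA4, a subunit of the respiratory chain, rose by 1.88. Housekeeping genes rose in 13 of 17 cases and fell in 2 (median 0.87, 0.78 and 1.00 in the sets, camera adjusted p = 0.0192, but adjusted p = 0.106 with an estimated correlation). ACTB, β-actin, rose by 2.42. Of 9 BMP target genes 8 rose and 1 fell (median 4.81, 5.70 and 4.08 in the sets, camera adjusted p = 0.00117, but adjusted p = 0.151 with an estimated correlation). ID1 rose by 4.35 and ID2 by 7.97. Inflammatory cytokines and chemokines rose in 10 of 14 cases and fell in 2 (median 2.46, 3.06 and 2.45 in the sets, camera adjusted p = 0.0233, but adjusted p = 0.425 with an estimated correlation), a call that was also lost with total library size only. The monocyte growth factor CSF1 rose from 17.3 ± 6.49 to 572 ± 33.9 CPM (5.05) and the chemokine CCL2 by 1.94. Smooth muscle contractile genes rose in 15 of 21 cases and fell in 5 (median 1.39, 1.34 and 1.26 in the sets, camera adjusted p = 0.0192, but adjusted p = 0.308 with an estimated correlation). Integrins and focal adhesion genes rose in 19 of 31 cases and fell in 8 (median 1.01, 1.08 and 0.86 in the sets, camera adjusted p = 0.0233, but adjusted p = 0.273 with an estimated correlation), a call also lost with log2(FPKM + 1). CAV1, the coat protein of caveolae, rose from 10.1 ± 1.87 to 564 ± 159 CPM (5.81).

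Lists of collagens, small leucine-rich proteoglycans and keratocyte markers fell with FBS. Collagens fell in 18 of 24 cases and rose in 2 (median -2.02, -2.10 in set 1 and -2.02 in set 2, camera adjusted p = 8.15e-06). COL11A1 (-3.69) and COL6A2 (-3.73) were among the lower and COL15A1 (4.48) among the higher. COL3A1 did not pass (17.6 ± 4.80 against 21.1 ± 12.5 CPM, 0.26, adjusted p = 0.379). It fell in set 1 (-0.67) and rose in set 2 (0.75, set-by-treatment edgeR adjusted p = 8.81e-05). Small leucine-rich proteoglycans fell in 10 of 11 cases and rose in 1 (median -4.26, -4.82 and -4.00 in the sets, camera adjusted p = 1.4e-06, but adjusted p = 0.0722 with an estimated correlation). Keratocyte markers fell in 12 of 13 cases (median -3.95, -4.03 and -3.41 in the sets, camera adjusted p = 1.63e-09). B3GNT7, an enzyme that extends keratan sulfate chains, fell from 159 ± 33 to 1.45 ± 0.353 CPM (-6.78), and ALDH1A1 (-2.65), CD34 (-4.20) and THY1 (-1.84) fell too, the last by more in set 1 (-3.22) than in set 2 (-0.97, set-by-treatment edgeR adjusted p = 3.71e-10). Cartilage, bone and tendon genes fell in 7 of 15 cases and rose in 3 (median -0.62, -0.59 and -0.89 in the sets, camera adjusted p = 0.00599, but adjusted p = 0.104 with an estimated correlation), a call also lost with no filter and with FPKM values. CHAD, the matrix protein chondroadherin, fell (-5.53). Matrix glycoproteins fell in 14 of 28 cases and rose in 7, and passed as a list within each set but not pooled (median -0.30, -0.21 and -0.45 in the sets, camera adjusted p = 0.0924). FN1 fell to 909 ± 219 CPM (-2.54) and MFAP4, a microfibril protein, from 1960 ± 320 to 31.6 ± 17.3 CPM (-5.96), whereas TGFBI rose to 1648 ± 273 CPM (1.75) and EFEMP1, a fibulin, by 5.24.

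IGF and insulin signaling genes fell with FBS in 17 of 19 cases and rose in 2 (median -1.98, -1.88 and -1.54 in the sets, camera adjusted p = 0.00241). IGFBP2, a binding protein for insulin-like growth factors, fell from 2561 ± 396 to 205 ± 79.4 CPM (-3.65). Complement genes fell in 11 of 14 cases and rose in none (median -2.28, -2.43 and -2.18 in the sets, camera adjusted p = 0.00316, but adjusted p = 0.193 with an estimated correlation). Vascular endothelial markers fell in all 5 cases (median -2.76, -1.61 and -2.96 in the sets, camera adjusted p = 0.0192, but adjusted p = 0.0722 with an estimated correlation), a call also lost with no filter, without FBS replicates 5 and 6 and in 11 of the 24 fits that left out a single library. KDR, a receptor for VEGF, fell from 305 ± 35.4 to 13.5 ± 1.53 CPM (-4.49).

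TGF-β target genes rose in 13 of 18 cases with FBS and fell in 2, just short of the threshold as a list (median 1.01, 1.15 in set 1 and 1.03 in set 2, camera adjusted p = 0.0533). The list passed with the replicate block (0.0212), within each set (0.00144 and 0.00347) and in 23 of 40 alternative settings in all. Immune cell markers did not pass either (2 of 5 rose and 1 fell, median 0.13, 0.10 and 1.20 in the sets, camera adjusted p = 0.118). They passed with the replicate block (0.0288), in set 2 alone (0.0292) and in 5 of 40 alternative settings in all, and not with counts summed per condition and set. LAPTM5 rose to 171 ± 25.1 CPM (5.41). Cholesterol synthesis genes rose in 11 of 22 cases and fell in 4 (median 0.46, camera adjusted p = 0.535), but the sets differed (set-by-treatment adjusted p = 6.25e-112, and 1.1e-07 with an estimated correlation). Their median was -0.05 in set 1 (adjusted p = 0.106) and 1.40 in set 2 (adjusted p = 6.53e-07). Collagen processing genes rose in 7 of 22 cases and fell in 11 (median -0.25, mean 0.01, camera adjusted p = 0.588), and glycosaminoglycan synthesis genes rose in 11 of 24 and fell in 10 (camera adjusted p = 0.729). Wnt pathway genes rose in 5 of 24 cases and fell in 11 (median -0.22, mean 0.03, camera adjusted p = 0.849 with its direction down). Fatty acid synthesis (5 of 12 rose and 6 fell, median -0.14, -0.33 in set 1 and 0.46 in set 2, camera adjusted p = 0.729, set-by-treatment adjusted p = 3.08e-16, and 8.08e-06 with an estimated correlation), glycolysis (11 of 21 rose and 8 fell, median 0.75, 0.451), p53 targets (10 of 17 rose and 5 fell, median 0.66, 0.22) and the unfolded protein response (12 of 20 rose and 3 fell, median 0.60, 0.0924, and 0.0224 in set 2 alone) did not pass.

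The edgeR test called 5257 genes higher and 5386 lower with FBS, 80% of those tested, 6188 of them by at least 2-fold, and in 7043 genes the 8 libraries of each group did not overlap. With total library size only the split was 6219 higher and 4450 lower (58.3% against 49.4% higher), with the median of all genes at 0.21. Adjusted over the list alone, the counts of this comparison given above were the same except that 11 glycosaminoglycan synthesis genes and 10 Wnt pathway genes fell. Among the largest changes, AQP3, a water and glycerol channel, had 2 counts in the serum-free group and 27484 with FBS, a ratio of 11652 (95% counting interval 3225 to 96222). SELP, P-selectin, had 0 counts without serum and 3527 with it, at least 997-fold more, and DKK1, a secreted Wnt inhibitor, at least 561-fold more. HAS2 rose from 0.149 ± 0.139 to 250 ± 67.6 CPM (10.66). FBP1, a gluconeogenic phosphatase, fell from 3625 counts to 1, a ratio of 4275 (767 to 168902). These intervals and floors cover counting error only.

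**Figure D2:**
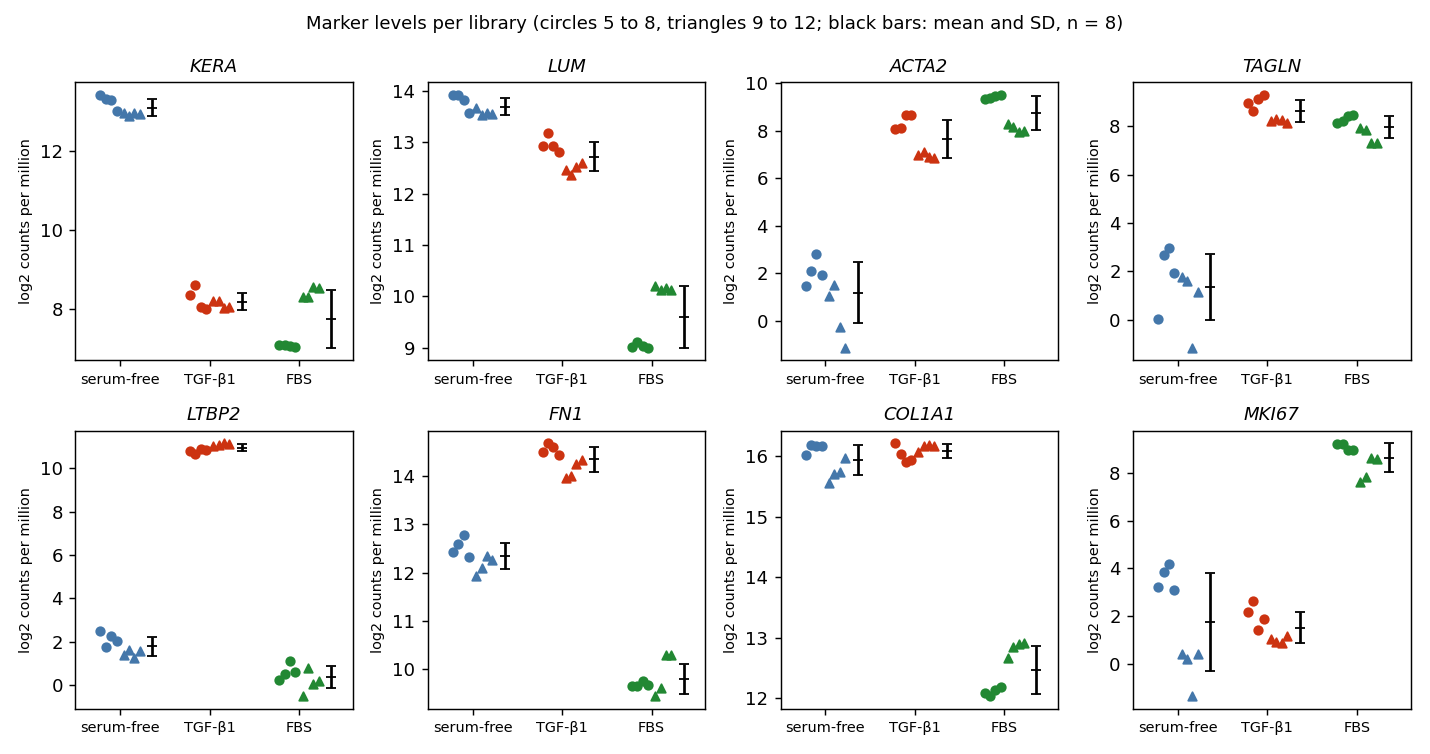
Log2 CPM of 8 genes in each library of the 3 conditions (circles, libraries 5 to 8, triangles, libraries 9 to 12), with the mean and SD of the 8 libraries as black bars. KERA is lower in all treated libraries than in all serum-free ones, LTBP2 is high with TGF-β1 alone, and MKI67 is high with FBS alone.

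How the myofibroblast and fibroblast conditions differ from each other is the question of the last comparison. Lists of collagens, collagen processing genes and matrix glycoproteins were higher and the list of DNA replication genes lower with TGF-β1. FN1 was 21157 ± 3768 CPM with TGF-β1 and 909 ± 219 CPM with FBS, 23.3-fold higher (log2 fold change 4.54, SE 0.17, edgeR adjusted p = 1.7e-18). COL1A1 was 11.9-fold higher (3.57) and ASPN 4445 ± 1727 against 10.1 ± 3.64 CPM (8.78). MKI67 was lower (-7.13). ACTA2, the usual marker of myofibroblasts, was lower with TGF-β1 than with FBS, 231 ± 125 against 479 ± 221 CPM (-1.05, SE 0.37, edgeR adjusted p = 0.0127, -1.02 in set 1 and -1.15 in set 2), though the libraries of the groups overlapped. TAGLN did not pass (0.67, adjusted p = 0.0531), but it passed with the replicate block (0.68, adjusted p = 0.00597) and within each set (0.71 and 0.60).

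Collagens were higher with TGF-β1 in 21 of 24 cases and lower in 1 (median 2.17, 2.5 in set 1 and 2.00 in set 2, camera adjusted p = 1.36e-10). Collagen processing genes were higher in 21 of 22 cases and lower in 1 (median 1.43, 1.35 and 1.49 in the sets, camera adjusted p = 6.06e-10), and matrix glycoproteins in 20 of 28 with 6 lower (median 2.00, 1.98 and 1.93 in the sets, camera adjusted p = 7.23e-06). COL11A1 (5.99), COL7A1, the anchoring fibril collagen (4.61), PLOD2 (4.34), POSTN (5.62) and VCAN (5.00) are examples, and EFEMP1 (-6.79) and TGFBI (-1.59) went the other way. Small leucine-rich proteoglycans were higher in 9 of 11 cases (median 3.04, 3.92 and 2.33 in the sets, camera adjusted p = 1.14e-07), and cartilage, bone and tendon genes in 13 of 15 with 2 lower (median 3.82, 3.40 and 3.87 in the sets, camera adjusted p = 3.62e-09). TGF-β target genes were higher in 14 of 18 cases and lower in 4 (median 1.16, 1.13 and 1.39 in the sets, camera adjusted p = 4.83e-05) and IGF and insulin genes in 14 of 19 with 4 lower (median 1.84, 1.78 and 1.89 in the sets, camera adjusted p = 0.00101). IGF1, the insulin-like growth factor itself, was 170 ± 93.3 against 1.39 ± 1.02 CPM (6.90). Fatty acid synthesis genes were higher in 11 of 12 cases and lower in 1 (median 1.93, 1.79 and 1.77 in the sets, camera adjusted p = 1.84e-06, but adjusted p = 0.0699 with an estimated correlation). Keratocyte markers were higher in 9 of 13 cases and lower in 2 (median 1.16, 1.22 and 0.85 in the sets, camera adjusted p = 0.00495, but adjusted p = 0.269 with an estimated correlation). LUM was 8.24-fold higher (3.04). KERA did not pass (0.30, adjusted p = 0.195), with 1.20 in set 1 and -0.30 in set 2. ALDH1A1 did not pass either (-0.18, adjusted p = 0.301), with 0.39 and -0.60. THY1 passed (0.87, adjusted p = 0.00908), though not with total library size only or with counts summed, and had opposite signs in the sets (2.39 and -0.21). The set-by-treatment term passed for each of them (edgeR adjusted p = 4.37e-08, 9.51e-09 and 1.24e-10).

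All 28 mitotic genes were lower with TGF-β1 than with FBS (median -6.46, -6.17 and -6.63 in the sets, camera adjusted p = 5.73e-16, but adjusted p = 0.131 with an estimated correlation). All 26 DNA replication genes were lower too (median -4.59, -4.78 and -4.29 in the sets, camera adjusted p = 2e-25). Of 20 oxidative phosphorylation genes 18 were lower (median -0.68, -0.45 in set 1, where the call was lost at adjusted p = 0.0745, and -0.87 in set 2, camera adjusted p = 0.00628, but adjusted p = 0.473 with an estimated correlation). Smooth muscle contractile genes did not pass as a list: 8 of 21 were higher and 6 lower (median -0.03, mean -0.08, 0.32 and 0.24 in the sets, camera adjusted p = 0.733 with its direction up). The replicate block added 7 lists to those called with all libraries. These were BMP targets (median -1.51, camera adjusted p = 0.113, and 0.0145 with the block), inflammatory cytokines (-0.90, 0.113 and 0.0426), the amino acid starvation response (0.11, 0.201 and 0.0425) and the Wnt pathway (0.92, 0.0531 and 0.0355). The others were growth factors and receptors (0.64, camera adjusted p = 0.113 and 0.0425), vascular endothelial markers (1.98, 0.0525 and 0.0425) and housekeeping genes (-0.58, 0.0885 and 0.0381). BMP targets also passed within each set (adjusted p = 0.008 and 0.0143), and the others except growth factors and receptors in set 2 alone. With counts summed per condition and set, the amino acid starvation response and growth factors and receptors did not pass. Cholesterol synthesis genes were higher in 17 of 22 cases and lower in 1 without passing (median 0.97, camera adjusted p = 0.0607), though they passed within each set (1.33 and 0.45, adjusted p = 1.08e-11 and 0.0105). Complement (9 of 14 higher and 1 lower, median 1.15, camera adjusted p = 0.0531, and 0.00554 in set 1 alone) and integrin genes (12 of 31 higher and 16 lower, median -0.35, 0.789) did not pass.

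The edgeR test called 4917 genes higher and 4840 lower with TGF-β1 than with FBS, 73.3% of those tested, 4806 of them by at least 2-fold. In 6145 genes the libraries of the groups did not overlap. With total library size only the split was 3131 higher and 6819 lower (31.5% against 50.4% higher), with the median of all genes at -0.39. Adjusted over the list alone, the counts above were the same except that 10 small leucine-rich proteoglycans were higher. LTBP2 (10.61) and CR2 (10.45) were again among the largest changes, and GDF10, a TGF-β family ligand, had 3061 counts with TGF-β1 and 0 with FBS, at least 1431-fold more. SELP had 0 counts with TGF-β1 and was at least 838-fold higher with FBS. STC1, the hormone stanniocalcin (-7.93), was among the lower genes.

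**Figure D3:**
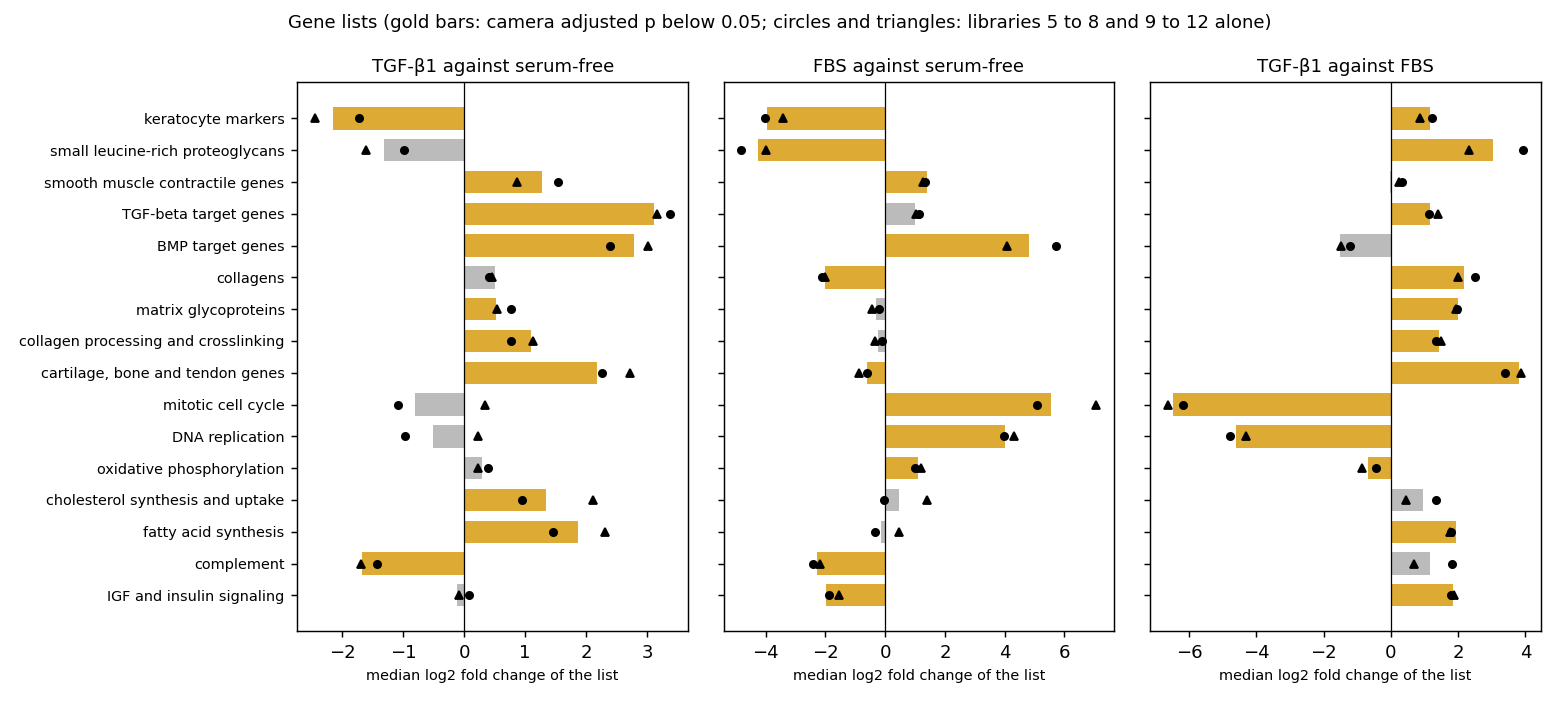
Median log2 fold change of 16 gene lists in the 3 comparisons (bars, gold where the camera adjusted p is under 0.05), with the medians in libraries 5 to 8 (circles) and 9 to 12 (triangles) alone. Collagens have medians of 0.51, -2.02 and 2.17 in the 3 comparisons, and mitotic genes of -0.80, 5.56 and -6.46.

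Set against serum-free medium, the treatments shared part of their changes. Of the genes called in both comparisons, 2751 were higher and 3118 lower in both, 711 were higher with TGF-β1 and lower with FBS, and 659 the reverse. Independent lists of these sizes would give 1641, 1784, 1682 and 1741. Both comparisons use the same serum-free libraries. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.535 and a Spearman correlation of 0.530, beside 0.495 and 0.457 in simulations of unchanged groups against the same controls. The covariance was 1.33, beside 0.0250 in the simulations. With the serum-free libraries split between the comparisons, the median over 35 splits was 5103 genes changed alike and 1077 oppositely, beside 5869 and 1370 with all of them. ACTA2, TAGLN, ANKRD1 and PLAUR (6.44 and 7.93) are examples of shared increases, and KERA, CD34 and ANPEP, a surface aminopeptidase (-4.66 and -6.09), of shared decreases. ASPN (4.42 and -4.36), CHAD (2.18 and -5.53), COL2A1 (2.15 and -4.74) and FMOD (2.37 and -4.26) rose with TGF-β1 and fell with FBS, and the opposite held for CCL2 (-3.18 and 1.94), EFEMP1 (-1.55 and 5.24) and IL1A, an interleukin-1 (-2.46 and 3.77). The fall of IL1A with TGF-β1 did not pass in set 1 (-0.92, adjusted p = 0.308, against -2.88 in set 2), and its rise with FBS was 5.76 and 3.04 in the sets (set-by-treatment adjusted p = 0.000636).

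Within the sets, 6650 genes were called in both sets with the same sign and 75 with opposite signs for TGF-β1 against serum-free, 9226 and 150 for FBS against serum-free, and 7876 and 178 for TGF-β1 against FBS. The log2 fold changes of the sets correlated across genes at 0.894, 0.933 and 0.913. The set-by-treatment term passed in 1368, 2977 and 3182 genes and in 13, 18 and 17 of the 39 lists, or 8, 10 and 9 with an estimated correlation.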

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

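The tests of single list members, of FBS replicates 5 and 6, of ACTA2, of immune cells and of other groupings of the samples were chosen after the result was seen. The tests of gene length, of neighbouring genes and of paralogs were written down before their values.

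Libraries lay far from the other 7 of their condition in 9 of 406 groups of values tested. Chance gives about 1 in 20, or 20.3, where the 8 values are independent draws from 1 normal distribution. Differences between the sets widen the range within a condition and can hide such libraries, so 9 cannot be judged against 20.3. Values are in log2 CPM. The mean of the small leucine-rich proteoglycans was 9.459 in serum-free replicate 4 (others 9.717 to 9.902) and 9.709 in TGF-β1 replicate 2 (others 9.151 to 9.399). The mean of the p53 targets was 5.488 in TGF-β1 replicate 4 (others 5.259 to 5.353). The mean of the Wnt pathway was 2.938 in TGF-β1 replicate 8 (others 3.059 to 3.165). The mean of the retinoid metabolism genes was 3.713 in serum-free replicate 1 (others 4.04 to 4.225). CDKN2B was at the floor of -3.227 in serum-free replicate 3 (others -1.278 to 0.4146). NR4A1 was 4.662 in TGF-β1 replicate 2 (others 5.087 to 5.292). CHAD was -0.6196 in FBS replicate 5 (others 0.04695 to 0.5571). FBP1 was -2.632 in FBS replicate 7, with the others at the floor of -3.227.

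Cholesterol synthesis genes responded to each treatment more in set 2 than in set 1, and the serum-free libraries themselves differed, with a list median 1.64 lower in set 2 (-1.635, camera adjusted p = 3.43e-30, and 0.0999 with an estimated correlation). Lists matched on gene length and level had medians around 0.008, with 95% of 10000 between -0.206 and 0.19, which argues against the trend of gene length between the sets as the source. FBS replicates 5 and 6, which stood apart from the others of their set, are not the source, since the FBS effect in set 2 without them had a median of 1.345. Nor are a few members, since 21 of 22 were lower in set 2 of the serum-free libraries. What the library-number sets were (days, animals or sequencing runs) is not given, and no biological explanation was tested.

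ACTA2 was higher with FBS than with TGF-β1. Wrong labels of single libraries are argued against by DNA replication genes and LTBP2, which put 0 libraries on the other condition's side. The difference held in each set (-1.02 in the set where it was smaller), so the sets do not account for it. It also held with other size factors (-1.052) and with total library size only (-1.462). Of 17 housekeeping genes 11 were lower and 2 higher with TGF-β1 than with FBS (median -0.575). Scaling to those genes was not run and would shrink the difference, so scaling is not excluded as a source. The FBS condition also had another base medium and fewer days of exposure, and 0 libraries part these from serum. Serum, medium and days therefore cannot be told apart as sources of the difference.

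LAPTM5, in most tissues a gene of blood cells, rose in each treatment. Immune cells would bring their abundant transcripts, but PTPRC, CD74, TYROBP and CYBB stayed at or under 0.1569% of the LAPTM5 level in every treated library. The highest was PTPRC. CD68, another immune cell marker of the list, went the other way. It was 2.34 ± 0.873 CPM in serum-free medium, 6.63 ± 0.992 CPM with TGF-β1 and 18.3 ± 5.98 CPM with FBS. The former markers thus argue against immune cells as the source, and CD68 does not. The only gene within 50 kb, MATN1, stayed at or under 0.3598% of the LAPTM5 level and does not overlap LAPTM5. Reads of the paralogs LAPTM4A and LAPTM4B are argued against by their summed level, which changed by -0.562 with TGF-β1 and by -1.59 with FBS. Expression of LAPTM5 by the treated cells themselves may be the source, as a hypothesis found and tested on these data.

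Other splits of the 16 libraries of each comparison gave fewer called genes than the real one. In each comparison 1 of 100 splits, the real one, reached the count. Splits that mix the conditions put the difference between them into the spread within a group, so this outcome was nearly fixed in advance. The test therefore cannot tell whether chance is a source of the counts. If the libraries of a condition are repeats of few cultures, a chance difference between those cultures is not tested by this. For TGF-β1 against serum-free the real split called 8591 genes and the highest other 5869, for FBS against serum-free 10245 and 8007, and for TGF-β1 against FBS 9386 and 7126. These were fitted on the 16 libraries alone. Each highest other split is the real one with 1 library moved each way, and it parts all same-numbered pairs, as do 50, 50 and 51 of the splits. Splitting by the sets called 2136, 958 and 826 genes.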

How the results depend on the processing

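The set as a covariate, each set alone, counts summed per condition and set, FBS replicates 5 and 6 left out, and the set-by-treatment term with an estimated correlation were chosen after seeing the data, and the other settings before the data were examined. With each library left out in turn, the number of genes higher ran from 4026 to 4292 for TGF-β1 against serum-free, from 5228 to 5376 for FBS against serum-free and from 4840 to 4995 for TGF-β1 against FBS. The number lower ran from 4305 to 4566, 5261 to 5502 and 4783 to 5003, and the lowest share of calls kept in direction was 95.9%, 98% and 97.3%. No list passed the threshold in the opposite direction in any setting. Called in both sets in the same direction were 6570, 9170 and 7841 of the genes called with all libraries. The replicate block ended the calls of the Wnt pathway and the glial markers for TGF-β1 against serum-free, added 2 lists for FBS against serum-free and 7 for TGF-β1 against FBS, and changed no other list call. The call of the glial markers (TGF-β1 against serum-free) ended without serum-free replicates 6 or 7, TGF-β1 replicates 1, 2 or 3, or FBS replicates 2 or 5, with adjusted p from 0.0321 to 0.0607 over all single libraries left out. That of the vascular markers (FBS against serum-free) ended without serum-free replicates 1, 3, 5, 6, 7 or 8, TGF-β1 replicates 5 or 6, or FBS replicates 6, 7 or 8 (0.0146 to 0.055). Depth limits genes with few counts, whose folds span their counting intervals. With counts summed per condition and set, only 2 sums stand for a condition, so fewer genes are called, while more lists passed than with all libraries (12 gained a call and 1 lost it over the 3 comparisons).

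The counts, shares and correlations that moved most are these, and the cause was not tested except where named. For TGF-β1 against serum-free, lists lower were 3 of 39 as reported, but 1 with total library size only, 1 with DESeq2, 1 with an estimated correlation, 7 with fry and 5 in set 1 alone. Lists higher were 18, but 5 with an estimated correlation. Genes changed at least 2-fold were 1925 with log2(FPKM + 1), where the added 1 shrinks low values, and genes lower were 2846 with counts summed. For FBS against serum-free, lists higher were 8, but 1 with an estimated correlation, 21 with fry and 16 in set 2 alone. Lists lower were 7, but 3 with an estimated correlation and 15 with fry. For TGF-β1 against FBS, genes higher were 3131 with total library size only, which puts the median of all genes at -0.39 where TMM gives 0.0069. Lists higher were 9, but 14 with total library size only and 24 with fry. Lists lower were 3, but 6 with only the 16 libraries compared, 6 with the replicate block, 5 with log2(FPKM + 1), 1 with an estimated correlation, 8 with fry, 6 with the set as a covariate, 6 in set 2 alone and 6 with counts summed. Genes changed at least 2-fold were 3126 with log2(FPKM + 1). The correlation of the log2 fold changes of the treatments was 0.5758 with no filter, 0.6046 with only the 16 libraries compared and 0.5662 with counts summed. Genes changed in opposite directions were 597 with counts summed. The share of variance on the leading pair of components was 94.2% with the most variable genes only and 86.1% with log2(FPKM + 1).

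Single genes reversed their sign within a set, and the cause was not tested: TGFBI in set 1 for TGF-β1 against serum-free (-0.2752), COL3A1 (-0.6671) in set 1 for FBS against serum-free, and, for TGF-β1 against FBS, KERA (-0.3007) and THY1 (-0.2061) in set 2 and ALDH1A1 (0.3855) in set 1. TAGLN for TGF-β1 against FBS passed in 18 of 38 settings, between 0.60 and 0.75. LUM and THY1 for TGF-β1 against serum-free did not pass with counts summed (-0.89 and -0.90). For the same comparison MKI67 passed with total library size only, with the set as a covariate, in set 1 and without any 1 of serum-free replicates 5, 6, 7 and 8 and TGF-β1 replicate 2. Lists with a set-by-treatment difference were 13, 18 and 17 in the 3 comparisons, but 8, 10 and 9 with an estimated correlation.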

Other observations

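The lists of this part other than the FOXO targets were fixed before the data were examined, and the tests of the mitotic genes in serum-free libraries were chosen after the result was seen. Several lists did not pass in any comparison with all libraries, although single members changed by much. Of 22 interferon-stimulated genes, 4 rose and 11 fell with TGF-β1 (median -0.62, camera adjusted p = 0.202), and 8 rose and 11 fell with FBS (median -0.45, 0.451). MX1, an antiviral GTPase, fell from 65.6 ± 4.30 to 9.24 ± 1.76 CPM with TGF-β1 and to 24.7 ± 10.4 CPM with FBS (mean ± SD, n = 8). OASL, an oligoadenylate synthetase-like protein, fell from 9.15 ± 2.32 to 3.81 ± 0.623 and 0.903 ± 0.714 CPM. Retinoid metabolism genes rose in 5 of 17 cases and fell in 7 with TGF-β1 (median -0.34, camera adjusted p = 0.194, and 0.0386 in set 2 alone), and rose in 4 and fell in 10 with FBS (median -0.70, 0.509). CRABP2, a retinoic acid carrier, fell from 126 ± 37.2 to 9.48 ± 3.37 and 40.6 ± 15.5 CPM, and the receptor RARB fell with TGF-β1 (-3.65) and was 8.43 ± 1.07 CPM with FBS against 7.78 ± 2.22 CPM without. Antioxidant genes under NRF2 rose in 6 of 20 cases and fell in 7 with TGF-β1 (median -0.20, mean 0.05, camera adjusted p = 0.777), and rose in 13 and fell in 4 with FBS (median 0.65, 0.584). SOD3, the extracellular superoxide dismutase, fell from 278 ± 30.2 to 116 ± 25.4 and 16.9 ± 7.31 CPM.

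Target genes of YAP and TEAD rose in 11 of 19 cases in either treatment and fell in 4 with TGF-β1 (median 0.41, camera adjusted p = 0.105) and in 5 with FBS (median 0.33, 0.835). With TGF-β1 the list passed upward within each set (0.0134 and 0.00907), with no filter, with fry and with counts summed per condition and set. CYR61, a matricellular protein, rose from 293 ± 203 to 1225 ± 313 and 923 ± 134 CPM, while F3, tissue factor, fell from 369 ± 50.8 to 155 ± 16.2 and 12.3 ± 2.45 CPM. Growth factors and receptors rose in 11 of 26 cases and fell in 8 with TGF-β1 (median 0.03, camera adjusted p = 0.351), and rose in 11 and fell in 14 with FBS (median -0.68, 0.535). The hepatocyte growth factor receptor MET was 3.06 ± 1.27, 2.46 ± 0.521 and 243 ± 97.8 CPM in serum-free medium, with TGF-β1 and with FBS, and the angiogenic factor VEGFA 77.6 ± 35.8, 557 ± 37.0 and 207 ± 30.3 CPM. Lipid storage and oxidation genes rose in 4 of 13 cases and fell in 5 with TGF-β1 (median -0.45, mean 0.21, camera adjusted p = 0.777), and 5 rose and 5 fell with FBS (median -0.26, 0.7 with its direction up). Corneal epithelial markers rose in 2 of 5 cases and fell in 1 with TGF-β1 (median 0.68, camera adjusted p = 0.327). They rose in 4 and fell in 1 with FBS (median 3.76, 0.0533, and 0.0396 in set 2 alone). There the list passed in 16 of 40 alternative settings, though not with no filter. Only 5 of the 17 listed markers in the table passed the filter. From serum-free medium to FBS, KRT19 went from 0.019 to 8.06, TP63 from 0.327 to 4.48 and DSG2 from 0.0839 to 2.15 CPM. Such genes pass the filter through treated libraries, so their rise is partly set by it. The epithelial genes KRT12, KRT5 and PAX6 were at 0, 0.0193 and 0.0122 CPM with FBS. Corneal endothelial markers rose in 5 of 10 cases in either treatment and fell in 4 with TGF-β1 (median 0.53, 0.222) and in 3 with FBS (median 0.26, 0.817), with COL8A2, a collagen of Descemet's membrane, at 1008 ± 116, 2586 ± 257 and 294 ± 39.8 CPM. Pericyte markers rose in 3 of 8 cases and fell in 3 in either treatment (medians -0.09 and 0.38, camera adjusted p = 0.398 and 0.588), and the FBS list had a mean of -0.65.

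The large falls of PDK4 (-8.15, with -5.34 in set 1 and -9.12 in set 2, set-by-treatment adjusted p = 7.29e-06) and PIK3IP1 (-4.35) with FBS raised the hypothesis of lower FOXO activity in serum, whose target list without those genes was written before its values were looked at. Of 12 targets tested, 10 fell and 1 rose with FBS (median -1.18, camera p = 0.0054, and 0.0307 with an estimated correlation), which the hypothesis needs. With TGF-β1, 7 rose and 3 fell (camera p = 0.0434, and 0.123 with an estimated correlation), and between the treatments 11 were higher with TGF-β1 and 1 lower (camera p = 2.2e-06). FOXO activity may thus be lower with FBS, but other regulators of the same genes were not tested.

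Mitotic genes were lower in set 2 than in set 1 of the serum-free libraries in 23 of 28 cases (median -2.09, camera adjusted p = 1.11e-11, and 0.392 with an estimated correlation). If the set 1 cultures held more dividing cells, DNA replication genes would be lower in set 2 too. Of 26, 11 were lower and 1 was higher (camera adjusted p = 0.000261, and 0.466 with an estimated correlation). A larger share of dividing cells in set 1 may be part of the difference between the sets, a hypothesis found and tested on the same libraries. Neither list passed with an estimated correlation.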
